A study of Mus musculus with 15 samples.

How the data were processed

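Total RNA of mouse neural stem and progenitor cells was sequenced in 15 libraries. The cells came from the dorsal telencephalon of embryos at embryonic day 12.5 and were grown as free-floating neurospheres with EGF and FGF. Per the labels, libraries were made with the TruSeq RNA prep kit v2 and sequenced on a NextSeq500 as 66 bp paired-end reads. Neither the strandedness of the library nor that of the counting is given in the sources used here, so values of genes that overlap another gene, on either strand, are uncertain. Genes with near-identical copies, such as the MHC class I, interferon-inducible Ifi20x, protocadherin and ribosomal protein families, are uncertain too, because reads may have been split between copies or dropped.

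The deposited files hold raw counts of reads or read pairs per gene. Per the submitters' processing notes, bcl2fastq and featureCounts were used with the mouse genome build mm10. Versions, aligner, annotation and counting settings are not given in the sources used here. The other deposited column, a gene length in bases as featureCounts reports it, was used only to tell unnamed entries apart. Entries without a gene name, 917 in each file, held 0.450% to 0.545% of the counts per library and were left out of library totals and tests. That left 26263 named genes, of which 96.2% were matched by gene identifier to coordinates of the mouse assembly GRCm38, the assembly of mm10. The total count over named genes ran from 12336303 to 62819028 per library.

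Samples were grouped by the genotype and background fields of the labels. Wild-type C57BL/6 libraries (WT_B6, n = 3, replicates 1, 2 and 4) were set against Kat6b knockout libraries on that background (KO_B6, n = 4). Wild-type libraries on a mixed FVB and BALB/c background (WT_FvB, n = 2) were set against libraries carrying a Kat6b transgene (Tg_FvB, n = 6). The titles of the Tg_FvB samples call them knockouts, while their genotype field and the series design call them transgenic. The count columns of Tg_FvB replicates 5 and 6 are headed as wild types 3 and 4 of the FvB background, and here too the genotype field was followed. WT_B6 replicate 1 and WT_FvB replicate 2 carry the same litter and embryo numbers.

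The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the counts as deposited. All 15 libraries entered 1 model with 1 coefficient per group, with TMM scaling and without covariates. Genes were kept by filterByExpr with a minimum count of 10, which left 15261 genes and removed 11002. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The tests covered 3 contrasts, namely KO_B6 against WT_B6, Tg_FvB against WT_FvB, and the difference of the 2 effects. CPM values are scaled by the TMM factors and are given as mean ± SD over libraries. Standard errors of log2 fold changes were derived from the F statistic. Kat6b itself was also compared by exact 2-sided permutation tests over all splits of the libraries. Folds against groups without any count were not computed, and a ratio resting on 1 to 3 counts is given with its exact 95% interval. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

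Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. The 39 lists covered neural lineages, chromatin complexes, cell cycle, signalling, metabolism and possible other cell types, and 35 of them had the 5 or more measured genes required. The lists, the groups, the main tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule named Kat6b, Kat6a and Sox2 in each comparison, and the 8 largest rises and 8 largest falls among called genes. Those genes needed a mean of at least 5 CPM, no overlap between the groups, and a symbol other than a Gm number, a Rik name or a pseudogene name. It also named up to 3 called members of each of the 6 lists with most calls, and up to 10 genes called in opposite and 5 called in the same direction in both comparisons. All members of the lists of KAT6 complexes and of chromosome 14 neighbours of Kat6b could be named. Other genes are marked as chosen after their values were seen.

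The tests were tried on simulated counts with known changes, drawn from the real means and library sizes. Every gene and library was drawn independently. The shares below therefore say nothing about errors from near-identical libraries or from genes that move together. In each simulation of single genes 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The real knockout comparison called 6982. The adjusted threshold is less strict when many genes change, so recovery there may differ. With 15 libraries and 15261 genes, the knockout comparison recovered 55.2% of 1.5-fold, 77.6% of 2-fold and 93.9% of 4-fold changes, and 6.79% of its calls were false. The transgenic comparison recovered 55.2%, 77.6% and 87.9% of these, and 3.92% of its calls were false. With near-identical libraries summed and 15958 genes, the knockout comparison recovered 0%, 20.9% and 71.2%, and 8.96% of its calls were false, while the transgenic comparison recovered 0%, 29.9% and 69.7%, and 2.94% of its calls were false. Camera found the 1 list that had been shifted in each simulation, and called 2 further lists in the knockout comparison with 15 libraries.

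Alternatives were RLE size factors, no low-count filter, a stricter filter of 1 CPM in 6 samples, DESeq2 1.42.0, limma-voom with sample quality weights, and a fit within each background. Further ones were litter as a covariate, the replicate number as a block, Y-linked counts as a covariate, leaving out each library, and fry for the lists. After seeing the data, 3 more were added. Near-identical libraries of a group were summed, Tg_FvB replicates 5 and 6 were left out, and all libraries were thinned to the depth of the shallowest. Libraries counted as near-identical when their pairwise biological coefficient of variation (BCV) over genes with a mean count of at least 50 was under 0.06. Genes private to 1 wild-type background had a mean of at least 2 CPM in its wild-type libraries and at most 3 counts in all wild-type libraries of the other background. A few genes that the fixed rule would have named are not reported here, and they were left out of the search for libraries far from their group. Figures were drawn with matplotlib 3.10.9. Splicing, exon use and sequence variants were not analysed here, since the values are sums per gene.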

Results

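RNA levels were measured in cultured neural stem and progenitor cells of the embryonic mouse forebrain. By the genotype field of their labels, the cells were wild type, knockout or transgenic for the histone acetyltransferase gene Kat6b. There were 3 WT_B6, 4 KO_B6, 2 WT_FvB and 6 Tg_FvB libraries. Total counts were 18483747, 30651056 and 31067022 in WT_B6 and 39413502, 56741179, 40821887 and 62819028 in KO_B6, so that every knockout library was deeper than every wild-type library it was compared with. In WT_FvB they were 19930942 and 21417513, and in Tg_FvB, from replicate 1 to 6, they were 21026396, 35994206, 22709206, 12336303, 23722124 and 41746720. Genetic background separated the libraries most, since the first principal component, with 47.9% of the variance, placed all B6 libraries below 0 and all FvB libraries above 0. Tg_FvB replicates 5 and 6 stood between them, at 3.94 and 4.81, while the other FvB libraries lay at 33.85 or higher.

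**Figure D1:**
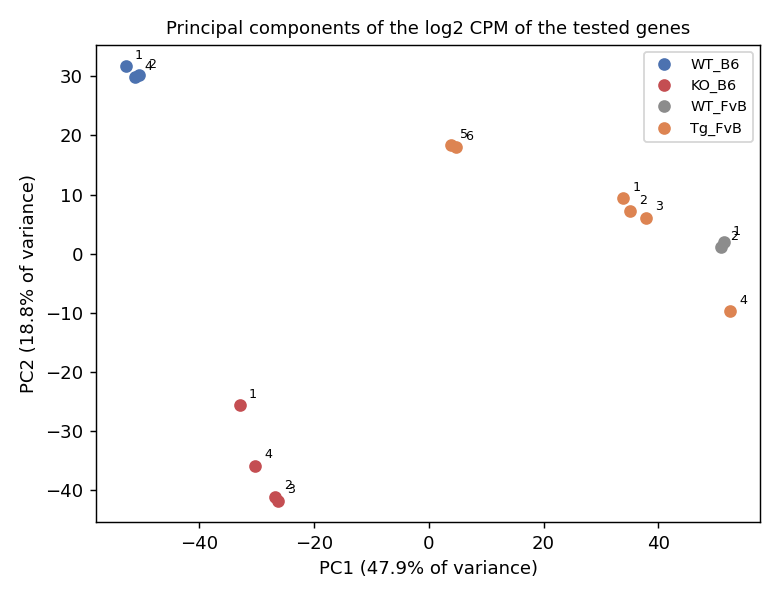
Principal components 1 (47.9% of variance) and 2 (18.8%) of the log2 CPM of the tested genes, 1 point per library with its replicate number. The 3 WT_B6 libraries lie almost on top of each other, and Tg_FvB replicates 5 and 6 lie at 3.94 and 4.81 on component 1, between the B6 and the FvB libraries.

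Kat6b (gene identifier 54169, chromosome 14, 21499216 to 21672478 in mm10) was lower in every knockout library and higher in every transgenic library than in its wild types. It averaged 84.2 ± 0.778 CPM in WT_B6 (n = 3) and 63.4 ± 2.22 CPM in KO_B6 (n = 4), so 75.2% of the wild-type level was still counted. The 4 knockout libraries had 61.0, 64.1, 66.1 and 62.3 CPM. The log2 fold change was -0.41 ± 0.17 (SE), which edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment did not call (adjusted p = 0.0571). Some alternatives called it, such as RLE size factors (adjusted p = 0.0453), while litter as a covariate did not (adjusted p = 0.143). The exact permutation test over the 35 splits gave p = 0.0286, the smallest it can give. It treats all libraries as independent, whereas the 3 WT_B6 libraries are near-identical, and so are KO_B6 replicates 2 and 3. Only 3 of the 35 splits keep near-identical libraries together, so this p may be too small. Within litter 843 the wild type had 84.1 CPM against 61.0 and 64.1 CPM, and within litter 929 it had 83.5 CPM against 66.1 and 62.3 CPM. The labels do not say which part of the gene the knockout allele lacks, and a sum over the whole gene cannot show the loss of single exons.

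The transgene's level was close to the roughly 4.5-fold overexpression stated for the line. Kat6b averaged 53.1 ± 1.80 CPM in WT_FvB (n = 2) and 242.8 ± 54.2 CPM in Tg_FvB (n = 6), a ratio of 4.57. It was called by edgeR with a log2 fold change of 2.19 ± 0.21 (SE) and an adjusted p of 2.38e-04. The exact permutation test over the 28 splits gave p = 0.0357, the smallest it can give. That test too counts near-identical libraries, both WT_FvB and Tg_FvB replicates 1 to 3, as independent, so its p may be too small. Single libraries stood at 5.05, 5.00, 5.01, 4.30, 2.63 and 5.44 times the wild-type mean, replicate 5 being the lowest. Within litter 844, which holds both wild types, the 2 transgenic libraries had 268.2 and 265.5 CPM, and litter 873 holds transgenic libraries only. Kat6a, the paralog of Kat6b, was called in neither comparison (log2 fold change -0.15, adjusted p = 0.0908 in the knockout; 0.04, adjusted p = 0.788 with the transgene).

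**Figure D2:**
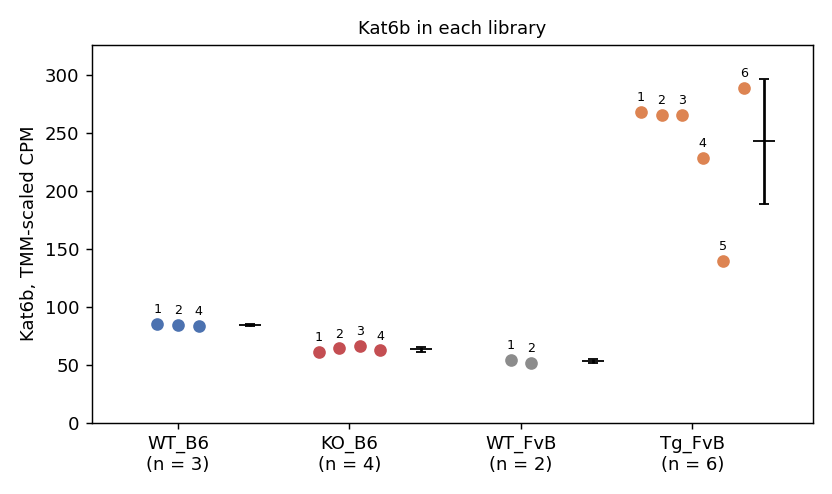
Kat6b in TMM-scaled CPM, 1 point per library with its replicate number, and the mean ± SD of each group at its right. The knockout libraries lie between 61.0 and 66.1 CPM and the transgenic ones between 139.6 and 288.9 CPM.

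The comparison of knockout with wild-type cells asks what the loss of Kat6b changes. By camera at its preset correlation, the lists of DNA replication, mitosis, cholesterol synthesis, glycolysis and hypoxia, growth factor feedback and immediate early genes shifted higher in the knockout. Those of SOX transcription factors, Notch pathway genes, clustered protocadherins, and genes of neural stem cells, astrocytes and oligodendrocytes shifted lower, although not all of their members were called. None passed with an estimated correlation (lowest adjusted p = 0.169). The stem cell factor Sox2 fell from 694.5 ± 17.2 to 472.6 ± 39.5 CPM (log2 fold change -0.56 ± 0.15, adjusted p = 0.00772).

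Replication genes rose as a block. Of the 22 DNA replication and G1/S genes measured, 22 were higher in the knockout and 0 lower (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.76 and a camera adjusted p of 7.17e-11 (adjusted p = 0.363 with an estimated correlation). The replicative helicase subunit Mcm6 rose from 170.8 to 300.2 CPM, the origin licensing factor Cdc6 rose 2.00-fold, and the thymidylate synthase gene Tyms rose 2.16-fold. The other wild type, WT_FvB, also lay above WT_B6 in these genes, at 234.9 CPM for Mcm6, 39.2 for Cdc6 and 41.7 for Tyms. Among 22 mitosis and G2/M genes 17 were higher and 0 lower (18 and 0 adjusted over the list alone; median 0.45, adjusted p = 3.01e-06, and adjusted p = 0.396 with an estimated correlation). They included Birc5, which encodes survivin (1.65-fold), the spindle motor gene Kif11 (1.39-fold) and the checkpoint kinase gene Bub1 (1.60-fold).

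Lists of lipid and energy metabolism genes shifted in the same direction. Of 20 cholesterol synthesis genes 18 were higher and 0 lower (18 and 0 adjusted over the list alone; median 0.65, adjusted p = 2.66e-08, and adjusted p = 0.363 with an estimated correlation). Of 18 glycolysis and hypoxia genes 12 were higher and 0 lower (15 and 0 adjusted over the list alone; median 0.81, adjusted p = 0.00257, and adjusted p = 0.5 with an estimated correlation). On the mean log2 CPM of that list, KO_B6 replicate 4 stood at 5.073, nearer to WT_B6 (4.697 to 4.861) than to the other knockouts (5.815 to 5.909). Adrenomedullin (Adm) and apelin (Apln), peptide genes that respond to low oxygen, rose 7.18-fold and 9.55-fold.

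The list of feedback genes of growth factor signalling also shifted higher. In the FGF, EGF and MAPK list 10 of 17 genes were higher and 3 lower (10 and 3 adjusted over the list alone; median 0.49, adjusted p = 0.00645, and adjusted p = 0.363 with an estimated correlation). Chosen after their values were seen, the ERK phosphatase gene Dusp6 rose from 35.9 ± 2.81 to 184.7 ± 16.2 CPM and the receptor signalling inhibitor gene Spry4 from 51.6 ± 1.38 to 211.0 ± 17.3 CPM, while the receptor gene Fgfr2 fell from 83.9 ± 2.81 to 31.0 ± 5.36 CPM. Of 16 immediate early genes 10 were higher and 2 lower (12 and 2 adjusted over the list alone; median 0.85, adjusted p = 0.0218, and adjusted p = 0.396 with an estimated correlation). Arc rose 7.99-fold, and Egr1, chosen after its values were seen, rose 3.41-fold.

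Lists of neural stem cell identity shifted lower. In the neural stem and radial glia list 11 of 18 genes were lower and 3 higher (11 and 3 adjusted over the list alone; median -0.38, adjusted p = 0.015, and adjusted p = 0.364 with an estimated correlation). The RNA-binding protein gene Msi1 fell from 88.3 to 44.8 CPM, Sox1 from 75.1 to 49.5 CPM and the endothelin receptor gene Ednrb from 1604 to 828.4 CPM. Of 13 SOX genes 10 were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.49, adjusted p = 0.00459, and adjusted p = 0.363 with an estimated correlation). Notch pathway genes were lower in 11 and higher in 3 of 20 cases (12 and 3 adjusted over the list alone; median -0.44, adjusted p = 0.00796, and adjusted p = 0.363 with an estimated correlation). Of these, chosen after their values were seen, the receptor gene Notch3 fell from 288.2 to 157.5 CPM and the ligand gene Jag1 rose from 18.4 to 46.4 CPM.

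The lists of glial genes shifted lower at the preset correlation, with 9 of 17 and 7 of 17 members called lower. Of 17 astrocyte genes 9 were lower and 1 higher (10 and 3 adjusted over the list alone; median -0.42, adjusted p = 0.0111, and adjusted p = 0.363 with an estimated correlation). The filament gene Gfap fell from 20.0 to 3.59 CPM, the lipid carrier gene Apoe from 1408 to 278.1 CPM and the water channel gene Aqp4 from 96.5 to 34.3 CPM. Of 17 oligodendrocyte genes 7 were lower and 1 higher (7 and 1 adjusted over the list alone; median -0.40, adjusted p = 0.0432, and adjusted p = 0.396 with an estimated correlation). That list did not pass with litter as a covariate (adjusted p = 0.0532), without a low-count filter (0.0536) or with near-identical libraries summed (0.0798). Neither did it without KO_B6 replicate 2, 3 or 4 (0.0533, 0.0729 and 0.0523) or WT_B6 replicate 2 or 4 (0.0556 and 0.0659). Sox10, chosen after its values were seen, fell from 67.1 to 35.9 CPM, and the receptor gene Gpr17 of early oligodendrocytes from 415.8 to 136.4 CPM.

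The list of clustered protocadherins shifted lower too. Of 43 gamma and beta protocadherins, which label the surface of single neurons, 23 were lower and 0 higher (25 and 0 adjusted over the list alone; median -0.48, adjusted p = 1.31e-05, and adjusted p = 0.169 with an estimated correlation). Pcdhb19 fell from 30.1 to 20.3 CPM, Pcdhb2 from 4.12 to 1.82 CPM and Pcdhb16 from 11.1 to 6.70 CPM. Axon guidance genes were lower in 14 and higher in 5 of 30 cases (14 and 5 adjusted over the list alone), but that list did not pass (adjusted p = 0.0884, and adjusted p = 0.396 with an estimated correlation) except without KO_B6 replicate 4 (0.0467) and with the replicate block (0.0384). Among them the ephrin receptor gene Epha4 fell from 33.1 to 14.6 CPM, the netrin receptor gene Unc5c fell from 14.6 to 8.37 CPM, and Plxna2 rose from 74.3 to 137.8 CPM.

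The largest changes of single genes lay outside these lists in part. They were ranked among called genes with a mean of at least 5 CPM and no overlap between the groups, so larger changes of scarcer genes are not among them. Besides Apln, Arc and Adm, the largest rises in that set were Erdr1 (log2 fold change 2.81), the neural transcription factor gene Pou3f1 (2.58), Diras2 (2.54), the potassium channel gene Kcnc4 (2.52) and the ligand gene Dhh (2.51). The largest falls in that set were those of the imprinted H19 transcript (-2.67), the cholesterol exporter gene Abca1 (-2.66), Kif19a (-2.49), Gfap (-2.43), Shisa9 (-2.43), the glucose-responsive Txnip (-2.38), Apoe (-2.34) and the inhibitor of differentiation gene Id4 (-2.31). Their adjusted p-values ran from 1.66e-06 for Apln to 0.00308 for Gfap. In mean CPM, WT_FvB stood nearer to KO_B6 than to WT_B6 for all these rises but Pou3f1. Kcnc4, for instance, had 7.14 CPM in WT_B6, 41.1 in KO_B6 and 43.8 in WT_FvB. Among the falls this held for Kif19a, Shisa9, Txnip and Id4, while H19, Abca1, Gfap and Apoe stood nearer to WT_B6. Whether WT_B6 stood apart through strain or culture was not tested. Partners of KAT6 proteins moved as well, with Ing5 (1.06), Jade3 (0.63) and Brpf1 (0.33) higher and Ing4 (-0.42) lower, although the list of 13, with 7 higher and 1 lower (8 and 1 adjusted over the list alone), did not pass (adjusted p = 0.135, and adjusted p = 0.363 with an estimated correlation). Of 11 chromosome 14 neighbours of Kat6b 6 were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.14, and adjusted p = 0.5 with an estimated correlation), among them the potassium channel gene Kcnma1 (1.11, adjusted p = 0.029).

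In all, edgeR called 3787 genes higher and 3195 lower in the knockout, 45.8% of those tested, and 532 and 650 of them changed more than 2-fold. The groups did not overlap in 8587 genes (56.3%). Chance gives 5.71% if all libraries are independent, and more if near-identical libraries are not, so no excess can be read from this share. With litter as a covariate 2886 were higher and 2380 lower, and 5229 of the calls were shared. WT_B6 replicate 1, alone in its litter, does not inform the effect in that fit. The 12 passing lists rest on camera's preset correlation, and none of the 35 tested lists passed with an estimated correlation. The other 23 did not pass, with adjusted p-values from 0.0884 for axon guidance to 0.949 for extracellular matrix genes, whose median was -0.09 and mean 0.09. Of these, p53 target and apoptosis genes (8 higher and 3 lower, adjusted p = 0.135) passed without KO_B6 replicate 1 (0.0394). The 3 WT_B6 libraries, from 3 litters, differed from each other by a BCV of only 0.0172 to 0.0358, and KO_B6 replicates 2 and 3 by 0.0268, against 0.113 to 0.161 between the other knockout pairs. When such near-identical libraries were summed, an alternative chosen after seeing the data, all 6982 genes kept their direction, but edgeR called 0 higher and 5 lower, with 3464 genes under an unadjusted p of 0.05, since the wild types then formed 1 profile and the median SE of the 6982 rose from 0.105 to 0.199. These 5, chosen after their values were seen, were Cyp2j13, Veph1, Emp1, Fam129a and Tekt5.

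**Figure D3:**
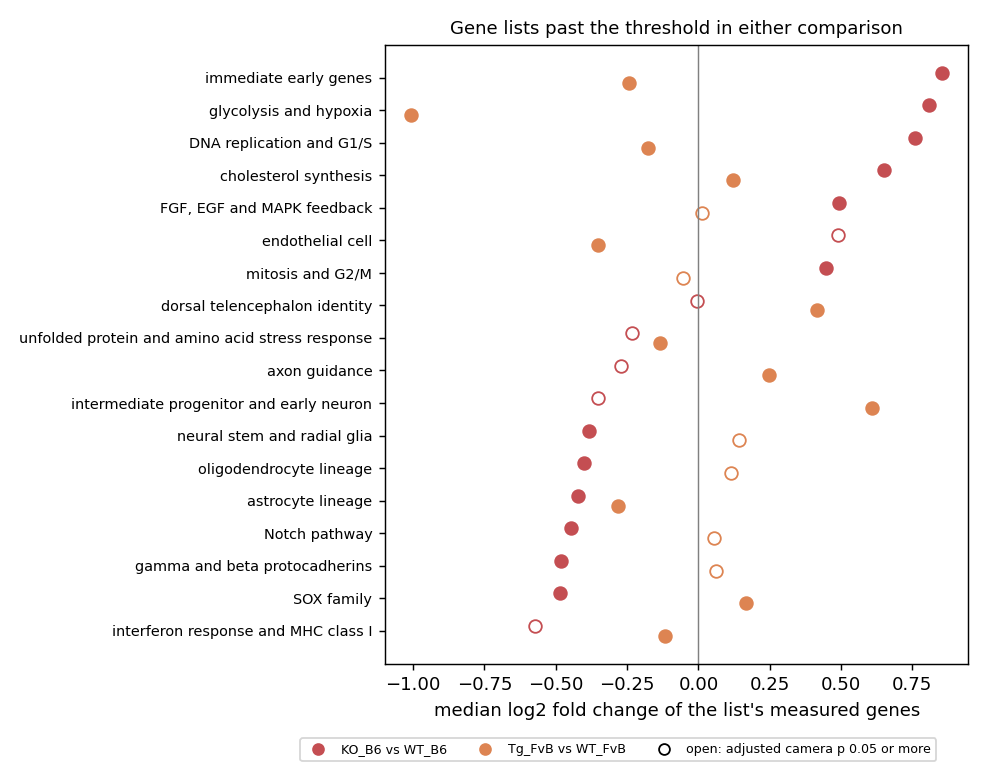
Median log2 fold change of the measured genes of each list that passed camera's adjusted threshold of 0.05 in either comparison, KO_B6 against WT_B6 in red and Tg_FvB against WT_FvB in orange, with open points for lists that did not pass there. The glycolysis and hypoxia list lies at 0.81 in the knockout and -1.01 with the transgene.

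The comparison of transgenic with wild-type cells asks what excess Kat6b changes. By camera at its preset correlation, the lists of glycolysis and hypoxia genes, of astrocyte genes and of replication genes shifted lower with the transgene. Those of intermediate progenitors and early neurons, of dorsal telencephalon identity, of SOX factors and of axon guidance shifted higher, with at most 2 members of each called higher. None of these lists passed with an estimated correlation (lowest adjusted p = 0.261). Sox2 was not called (426.0 ± 30.3 against 523.9 ± 111 CPM, log2 fold change 0.30 ± 0.17, adjusted p = 0.351).

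Of 18 glycolysis and hypoxia genes 7 were lower and 0 higher (17 and 0 adjusted over the list alone; median -1.01, adjusted p = 5.04e-18, and adjusted p = 0.342 with an estimated correlation). The glucose transporter gene Slc2a1 fell from 108.7 ± 3.12 to 40.9 ± 15.3 CPM, Pgam1 from 164.3 to 115.0 CPM and Pgk1 from 137.1 to 87.5 CPM. The hypoxia-responsive Ndrg1 fell from 93.7 ± 0.805 to 13.9 ± 8.49 CPM. On the mean log2 CPM of the list the 2 wild types stood at 7.05, and the transgenic libraries lay between 5.00 for replicate 6 and 6.52 for replicate 4. Without replicates 5 and 6 the median was -0.85.

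**Figure D4:**
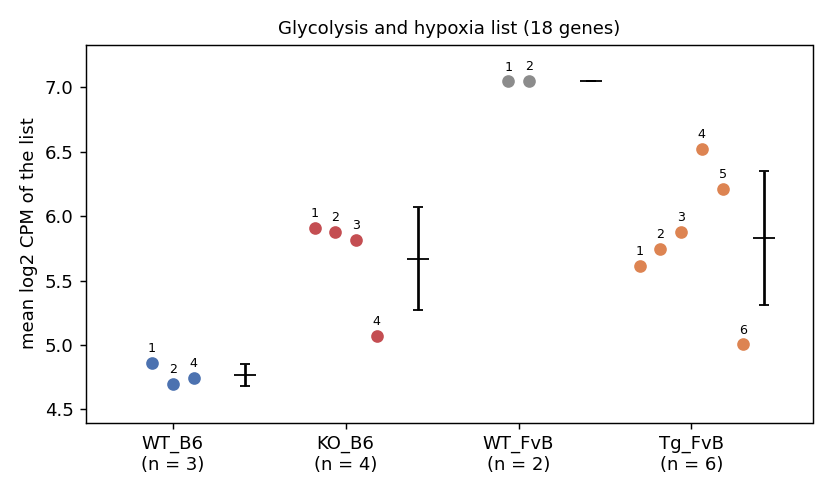
Mean log2 CPM of the 18 glycolysis and hypoxia genes, 1 point per library with its replicate number, and the mean ± SD of each group at its right. Both WT_FvB libraries lie at 7.05, above all others, and the WT_B6 libraries lie lowest, between 4.70 and 4.86.

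Astrocyte genes were lower in 5 and higher in 0 of 17 cases (5 and 0 adjusted over the list alone; median -0.28, adjusted p = 4.48e-05, and adjusted p = 0.261 with an estimated correlation). Gfap fell from 158.4 ± 1.21 to 35.3 ± 23.4 CPM, the matrix protein gene Sparcl1 from 312.6 to 65.8 CPM, Clu from 90.2 to 31.8 CPM and Aqp4 from 164.4 to 86.4 CPM. The metallothionein gene Mt1 fell from 249.0 to 171.0 CPM. Lists without a single called gene also passed on small common shifts. These were DNA replication (22 genes, median -0.17, adjusted p = 1.76e-04, and adjusted p = 0.632 with an estimated correlation), immediate early genes (16 genes, median -0.24, adjusted p = 0.0123, and adjusted p = 0.445 with an estimated correlation) and cholesterol synthesis (20 genes, median 0.12, adjusted p = 0.0118, and adjusted p = 0.679 with an estimated correlation), the last of which did not pass with near-identical libraries summed (0.0553). The stress response list (15 genes, median -0.13, adjusted p = 0.0424) and the endothelial list (8 genes, median -0.35, adjusted p = 0.0295) had 1 higher and 5 lower, and 0 higher and 3 lower, when adjusted over the list alone, and both had an adjusted p = 0.342 with an estimated correlation. The endothelial list did not pass with litter as a covariate (0.0676), the replicate block (0.0991), no low-count filter (0.262) or near-identical libraries summed (0.0546). It also failed without Tg_FvB replicates 5 and 6 together (0.12), without either of these alone (0.0537 and 0.0545) and without WT_FvB replicate 2 (0.0729). The stress response list did not pass with near-identical libraries summed (0.0893), without Tg_FvB replicate 1, 2, 3 or 4 (0.0663, 0.0664, 0.0687 and 0.0651) or without WT_FvB replicate 2 (0.0669). Interferon and MHC class I genes had 1 of 19 lower (1 adjusted over the list alone; median -0.12, adjusted p = 0.047, and adjusted p = 0.342 with an estimated correlation). They did not pass without a low-count filter (0.108), with near-identical libraries summed (0.115), without Tg_FvB replicate 1, 2, 3 or 4 (0.0663, 0.0859, 0.0684 and 0.0651) or without WT_FvB replicate 2 (0.308).

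Genes of intermediate progenitors and early neurons shifted higher as a list. Of 17 intermediate progenitor and early neuron genes 2 were higher and 1 lower (9 and 3 adjusted over the list alone; median 0.61, adjusted p = 0.0118, and adjusted p = 0.342 with an estimated correlation). The RNA-binding protein gene Elavl3 rose from 27.0 ± 0.198 to 41.0 ± 4.98 CPM and the proneural gene Neurod1 from 0.0474 to 0.565 CPM, while Hes6 fell from 153.5 to 116.5 CPM. The WT_FvB level of Neurod1 is near the floor and rests on very few counts, so the size of its rise is uncertain. The list of mature neuron and synapse genes did not pass (adjusted p = 0.529, and adjusted p = 0.697 with an estimated correlation), although 2 of its 22 genes were higher (2 adjusted over the list alone; median 0.062). These were the synaptic vesicle gene Syp, from 9.07 to 14.3 CPM, and the neuronal splicing factor gene Rbfox3, from 0.358 to 2.06 CPM. Of 12 dorsal telencephalon genes 0 were called (1 higher adjusted over the list alone; median 0.41, adjusted p = 0.0131, and adjusted p = 0.428 with an estimated correlation), and of 30 axon guidance genes 1 was higher (1 adjusted over the list alone; median 0.25, adjusted p = 0.0123, and adjusted p = 0.342 with an estimated correlation, and 0.114 with the replicate block). Of 13 SOX genes 2 were higher and 0 lower (3 and 0 adjusted over the list alone; median 0.17, adjusted p = 0.013, and adjusted p = 0.445 with an estimated correlation), namely Sox10, from 17.4 to 39.7 CPM, and Sox1, from 53.6 to 66.3 CPM. The SOX list did not pass with near-identical libraries summed (0.0616), without Tg_FvB replicates 5 and 6 (0.0547) or without replicate 5 alone (0.0671).

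Besides Kat6b, and again among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises were those of the secreted WNT modulator gene Dkk3 (log2 fold change 2.27), the deubiquitinase gene Stambpl1 (2.16), H2-T22 (2.10), Dach1 (1.74), Dynlt1b (1.64), Fgf12 (1.47) and Gpr17 (1.33). The largest falls in that set were Ndrg1 (-2.80), Ifi203 (-2.60), Sparcl1 (-2.25), Gfap (-2.18), Loxl2 (-1.95), Scd4 (-1.87), H2-T10 (-1.69) and Kcnma1 (-1.66). Their adjusted p-values ran from 0.00271 for Stambpl1 to 0.0499 for Ifi203. H2-T22, H2-T10 and Ifi203 belong to families that differ between mouse strains, and Ifi203 had 262.4 CPM in WT_FvB against 0.0325 CPM in WT_B6. Dupd1, which starts just beyond Kat6b on chromosome 14 (21676565 to 21714576), had 288 counts in the 6 transgenic libraries, 16 to 93 in each, and 2 counts in WT_FvB, a ratio of 38.7 (95% interval 10.6 to 321). Adamts10, a matrix protease gene chosen after its values were seen, rose from 10.9 ± 1.27 to 20.0 ± 0.691 CPM. Its log2 fold change was 0.985 without WT_FvB replicate 1 and 0.754 without replicate 2. Adamts10 stood at 47.5 to 54.6 CPM in KO_B6, so its level also differed between B6 and FvB libraries. Whether a strain difference within the mixed FVB and BALB/c background gave its rise was not tested.

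In all, edgeR called 105 genes higher and 178 lower with the transgene, 1.85% of those tested. The groups did not overlap in 2439 genes (16.0%). Chance gives 7.14% if all libraries are independent, and more if near-identical libraries are not, so here too no excess can be read from the share. Litter 844 holds both wild types and Tg_FvB replicates 1 and 2, and each of these pairs is near-identical. With litter as a covariate the transgene effect rests on these libraries alone, and 6 genes were higher and 4 lower. With only 2 wild types the number of calls rested on single libraries: 2 calls, Kat6b and Adamts10, were kept without either WT_FvB replicate 1 or 2, 59, 62 and 88 calls were kept without Tg_FvB replicate 1, 2 or 3, and 216 genes were higher and 390 lower without replicate 5. Without Tg_FvB replicate 4, 963 were higher and 800 lower. That library was the shallowest, and it also lay nearer to the WT_FvB libraries (BCV 0.098 and 0.089) than to any other transgenic library (BCV 0.131 to 0.253). The WT_FvB pair differed by a BCV of 0.0315 and Tg_FvB replicates 1, 2 and 3 by 0.0338 to 0.05, and with these summed edgeR called 0 genes, with 471 under an unadjusted p of 0.05, fewer than the 798 expected by chance. No list passed with an estimated correlation here either. The 23 lists that did not pass had adjusted p-values from 0.0694 for oligodendrocyte genes to 0.823 for SHH pathway genes. Of these, p53 target and apoptosis genes passed with litter as a covariate (0.0301) and with the replicate block (0.00888), and neural stem and radial glia genes with the replicate block (0.0187) and without Tg_FvB replicate 4 (0.0438). Oligodendrocyte genes passed without a low-count filter (0.0276), without Tg_FvB replicate 4 (0.0205) and without WT_FvB replicate 2 (0.0468).

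Tg_FvB replicates 5 and 6 held more of some B6 transcripts than most other FvB libraries. For 9 genes on 5 chromosomes that were private to the wild-type B6 libraries, among them H2-T24, Ccl21b and Gm6436, the median level was 57.8% of that in WT_B6 in replicate 5 and 10.2% in replicate 6. It was at most 0.304% in the other transgenic libraries, where 3 to 5 of the 9 genes still had reads and H2-T24 stood higher in replicate 4 than in replicate 6, and 52.3% to 74.6% in the KO_B6 libraries, so the level of these genes also differed within B6. Some of the 9 are near-identical copies that share reads. The reverse set did not settle the source: for 8 genes private to the WT_FvB libraries, among them Ifi203, Mndal and Sycp1, the median level was 17.4% to 47.9% of that in WT_FvB in transgenic replicates 1 to 4, 22.7% in replicate 5 and 2.98% in replicate 6. Without replicates 5 and 6 edgeR called 216 genes higher and 422 lower with the transgene, and 265 of the 283 calls were shared.

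**Figure D5:**
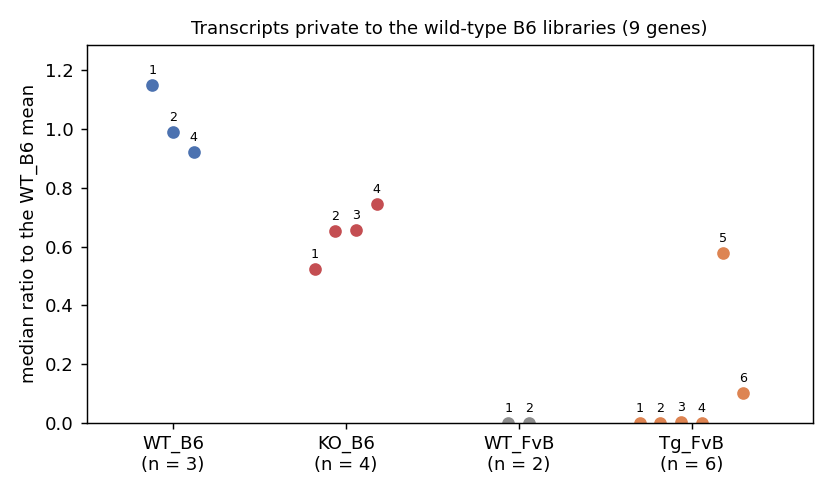
Median ratio to the WT_B6 mean over 9 genes private to the wild-type B6 libraries, 1 point per library with its replicate number. Tg_FvB replicate 5 lies at 0.578 and replicate 6 at 0.102, while all other FvB libraries lie at 0.003 or lower.

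The difference of the 2 effects asks which genes respond unequally to loss and gain. A gene that changed in the knockout alone also counts there, so a call does not mean opposite responses. Across the 15261 genes the log2 fold changes had a Pearson r of -0.17 and a Spearman rho of -0.25, and 59.6% of genes had opposite signs, though genes are not independent replicates. The Pearson r was -0.044 without Tg_FvB replicates 5 and 6, -0.12 without replicate 5 alone, -0.069 without a low-count filter, -0.083 with the replicate block and -0.095 with litter as a covariate. If Tg_FvB replicates 5 and 6 hold wild-type B6 RNA, the 2 comparisons are not independent. The control of the knockout comparison would then enter the transgenic arm and push the correlation below 0. Glycolysis and hypoxia genes differed most in size, with 18 of 18 higher in the contrast of knockout minus transgene effect (18 adjusted over the list alone; median 1.98, adjusted p = 9.55e-09, and adjusted p = 0.334 with an estimated correlation). All 22 replication genes differed too (22 adjusted over the list alone; median 0.95, adjusted p = 3.97e-12, and adjusted p = 0.334 with an estimated correlation), as did SOX genes with 9 lower and 1 higher (10 and 1 adjusted over the list alone; median -0.62, adjusted p = 8.44e-04, and adjusted p = 0.334 with an estimated correlation). In single genes edgeR called a difference for 5695, among them Kat6b (adjusted p = 6.07e-05) and Sox2 (log2 difference -0.85, adjusted p = 0.00900). The count was 9577 with limma-voom, whose sample weights favoured near-identical libraries, and 2862 with litter as a covariate. It was 0 by edgeR with near-identical libraries summed, with 2803 under an unadjusted p of 0.05.

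Genes called in both comparisons were about as often opposite as independent lists would be. There were 78 with opposite direction, where 66.2 are expected of independent lists, and 63 with the same direction, where 63.4 are expected. The number of opposite genes rested on single libraries too, with 0 left without either WT_FvB library, 11 to 38 without Tg_FvB replicates 1, 2 or 3, KO_B6 replicates 2 or 3 or any WT_B6 library, 128 without Tg_FvB replicate 5 and 866 without Tg_FvB replicate 4. Opposite genes included Ndrg1 (2.10 in the knockout and -2.80 with the transgene), Dkk3 (-1.97 and 2.27), Gpr17 (-1.61 and 1.33), the perineuronal net gene Tnr (-1.35 and 1.27) and Flvcr2 (-1.30 and 1.52). Tnr stood at 111 CPM in Tg_FvB replicate 5 and at 44.3 to 66.8 CPM in the other transgenic libraries. Fkbp5, a glucocorticoid-induced chaperone gene chosen after its values were seen, rose 1.64-fold in the knockout and fell from 74.5 to 35.5 CPM with the transgene, and it was the 1 opposite gene left with litter as a covariate. Dlx3, Plxdc1, C3, Adra1d and Tunar were opposite too, but stayed under 1 CPM in every group, and Tunar had no count in WT_FvB against 0.226 CPM in Tg_FvB. Gfap fell in both comparisons, as did Ahnak (-2.26 and -1.90), Gng4 (-2.03 and -1.94) and Fxyd1 (-2.47 and -2.15), and Neurod1 rose in both from under 0.11 CPM.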

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

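All tests of explanations in this part were chosen after the result was seen, except the counts over all 35 splits of the B6 libraries.

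The first pattern is the 6982 genes called between knockout and wild type. Only 1 of the 35 splits of the 7 B6 libraries into groups of 3 and 4, the real one, reached that number (highest other 4438). Near-identical libraries may not be independent, however, and the 3 splits that keep them together are too few for a share under 0.05. For the 12 gene lists chance cannot be excluded, because 6 of the 35 splits gave as many and the highest other gave 14. A difference in library depth is argued against as the whole source, since 6135 genes were still called after all libraries were thinned to equal depth. Near-identical libraries tested as separate replicates stay open as a source: after summing them edgeR called only 5, but the 3 wild types then counted as 1 profile and the median SE of the 6982 genes rose from 0.105 to 0.199, while their median absolute log2 fold change went from 0.50 to 0.49 and all kept their direction. The loss of Kat6b stays open too, because 3464 genes, 3403 of the 6982 among them, had an unadjusted p under 0.05 in that fit where 798 are expected by chance, but with 1 distinct wild-type profile a difference of genotype cannot be told apart from a difference of that culture.

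The second pattern is the B6-private transcripts in Tg_FvB replicates 5 and 6. A wild-type library in place of a transgenic one, as the column headers of both read, is argued against by Kat6b, which was at least 2.63 times the WT_FvB mean in each. Inherited B6 chromosome segments in replicate 6 would give levels near those of 0, 1 or 2 copies, but 8 of the 9 private genes lay between 0.03 and 0.3 of the wild-type B6 level. That window is not strict, since 1 of the 9 also lay in it in each of KO_B6 replicates 2 and 3, which are B6 by label. RNA or cells of B6 origin in replicate 6 are a candidate explanation, since 7 of the 9 genes, on several chromosomes, lay within 2-fold of 1 common share of 0.102. However, Gm21541, Gm13304, Ccl21b and Gm10591 all lie on chromosome 4 and may not be separate readings. Genes private to WT_FvB did not bear this origin out, with a median of 2.98% of the WT_FvB level in replicate 6 against 17.4% to 47.9% in replicates 1 to 4. For replicate 5 the common share was 0.578, the highest of the group and far from the others. It could come from RNA or cells of B6 origin or from 1 B6 chromosome set of 2. The profile of replicate 5 was about as near to WT_B6 (BCV 0.169 to 0.172) as to Tg_FvB replicate 3 (BCV 0.169). It lay farther from KO_B6 (BCV 0.224 to 0.232). These distances do not tell the 2 origins apart, and no other biological explanation was tested.

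The third pattern is the lower glycolysis and hypoxia RNA with the transgene. B6 RNA in replicates 5 and 6 is argued against as its whole source, because the list's median stayed at -0.85 without them. Both WT_FvB libraries, which form 1 distinct profile, lay at least 0.524 above all 13 other libraries on the list's mean log2 CPM, so that a wild-type culture that stands apart, for instance in density or oxygen, may explain the fall. A dose effect of Kat6b would also raise the list in the knockout, where it was higher under the preset correlation but had an adjusted p of 0.5 with an estimated one. Neither explanation can be excluded with 1 distinct wild-type profile.

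Of 186 groups of 4 or 6 values checked for a library far from the rest, 27 had one. Chance gives about 1 in 20 if all libraries are independent, and near-identical libraries may not be. Every library that stood apart lacked a near-identical partner, so no excess can be read from this share. In Tg_FvB replicate 5, 12 values stood apart, its B6-private share among them. Kat6b was lowest there at 140 CPM, as were Tyms at 29.4, Birc5 at 80.2, Brpf1 at 46.2, Dusp6 at 77.1, Dupd1 at 0.667 and Neurod1 at 0.208 CPM. H19 at 15.1, Kif19a at 7.76, Notch3 at 245 and Fam129a at 5 CPM were highest there. Tg_FvB replicate 4, the shallowest library, was lowest in 8 genes, namely Apoe at 602, Msi1 at 45.1, Fgfr2 at 50.8, Adamts10 at 18.7, Epha4 at 17.1, Dach1 at 3.56, Dkk3 at 2.14 and Rbfox3 at 0.554 CPM. Ifi203 was lowest in Tg_FvB replicate 6 at 2.11 CPM.

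KO_B6 replicate 1 was lowest in Apln at 45 CPM, Kcnc4 at 20.3 CPM and Dhh at 7.69 CPM. KO_B6 replicate 4 was highest in Erdr1 at 32.3 CPM and lowest in Fkbp5 at 48.9 CPM and in the mean of the glycolysis and hypoxia list at 5.073 log2 CPM. It is also the only library with Y-linked reads, 18532 counts of Ddx3y, Eif2s3y, Kdm5d and Uty against at most 5 in every other. Outside the tested genes, 1 unnamed entry of 1139 bases had 213 counts in the 6 Tg_FvB libraries, 17 to 63 in each, and 0 in the 9 other libraries.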

How the results depend on the processing

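Summing near-identical libraries, leaving out Tg_FvB libraries 5 and 6, and thinning to equal depth were chosen after the data were seen, and the other alternatives beforehand. Of the values that answer a comparison, 138 stayed on the same side of the threshold or within their spread, 78 moved, 7 went past the threshold, 1 fell short of it and 0 changed direction. Of the values of single genes 1662 stayed on the same side, 394 lost their call, 15 gained one and 0 changed direction. Except where an alternative's construction is named, the cause was not tested. Limma-voom gave libraries with a near-identical partner weights of 1.16 to 3 and all others 0.181 to 0.306. Its counts therefore lean on near-identical libraries taken as separate replicates.

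The knockout counts of 3787 higher and 3195 lower held within 1.5 times under all alternatives chosen beforehand but 1: limma-voom with sample weights called 5139 lower. Leaving out 1 library gave 2767 to 3529 higher and 2592 to 3633 lower. Summing near-identical libraries gave 0 higher and 5 lower in edgeR, with 3464 under an unadjusted p of 0.05, by construction from fewer replicates. Kat6b in the knockout missed the threshold at -0.41, and passed it with RLE size factors (-0.44), the strict filter (-0.44), DESeq2 (-0.44), limma-voom (-0.38), a fit within 1 background (-0.42), thinning (-0.44) and without Tg_FvB libraries 5 and 6 (-0.44). Its adjusted p ran from 2.3e-05 without Tg_FvB libraries 5 and 6 to 0.418 with near-identical libraries summed (-0.46), and its log2 fold change from -0.46 to -0.40 without 1 B6 library.

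The transgene counts of 105 higher and 178 lower held within 1.5 times with RLE size factors, both other filters, the Y-linked covariate and without Tg_FvB replicate 6, and moved otherwise. DESeq2 gave 356 and 368, limma-voom 2767 and 2557, a fit within 1 background 3 and 7, and the litter covariate 6 and 4. Without Tg_FvB libraries 5 and 6 there were 216 and 422, after thinning 47 and 111, and with near-identical libraries summed 0 and 0 in edgeR. In that fit 471 genes were under an unadjusted p of 0.05, fewer than the 798 expected by chance. All 283 called genes kept their direction, their median absolute log2 fold change went from 0.97 to 0.91 and their median SE rose from 0.198 to 0.321. Leaving out 1 library gave 2 to 963 higher and 0 to 800 lower. Without WT_FvB replicate 1 or 2, where the remaining wild type is assumed to vary like the other groups, 2 were higher and 0 lower, with 1335 and 1393 under an unadjusted p of 0.05. Without Tg_FvB replicate 1 there were 23 and 36, without replicate 2 21 and 41, without replicate 3 29 and 59, without replicate 4 963 and 800, and without replicate 5 216 and 390. Within 1 background the 3 higher were Kat6b, Adamts10 and H2-Q6, and with litter the 4 lower were Mt1, Fkbp5, Rps28 and Col5a2, all but Kat6b and Mt1 chosen after their values were seen. Kat6b with the transgene stayed past the threshold in all alternatives but the summed one (2.12, adjusted p = 1, unadjusted 2.87e-04), with adjusted p-values otherwise from 4.06e-27 to 0.0407, the latter without WT_FvB replicate 2, and log2 fold changes of 2.13 to 2.30 without 1 FvB library.

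The 5695 genes whose effects differ became 9577 with limma-voom, 2862 with litter 0 in edgeR with near-identical libraries summed (2803 under an unadjusted p of 0.05), and 3598 to 6760 without 1 library, with 3598 and 3656 without WT_FvB replicates 1 and 2. The correlation of -0.17 became -0.069 without a low-count filter, -0.21 with the strict one, -0.13 with DESeq2, -0.10 with limma-voom, -0.20 within 1 background, -0.095 with litter, -0.044 without Tg_FvB libraries 5 and 6, and -0.21 to -0.12 without 1 library. The 78 opposite genes became 246 with DESeq2, 2419 with limma-voom, 144 without Tg_FvB libraries 5 and 6, 41 after thinning, 2 within 1 background (Kat6b and Fkbp5), 1 with litter (Fkbp5) and 0 with near-identical libraries summed. Leaving out 1 library gave 0, without either WT_FvB library, to 866, without Tg_FvB replicate 4. It gave 24, 26 and 26 without WT_B6 replicates 1, 2 and 4, 38 and 31 without KO_B6 replicates 2 and 3, and 11, 14, 27 and 128 without Tg_FvB replicates 1, 2, 3 and 5.

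Of the gene lists, 12 passed in each comparison. With an estimated correlation 0 passed in both. By fry, which tests whether a list's genes move one way and not whether they do so more than others, 26 passed in the knockout and 2 with the transgene. With near-identical libraries summed 7 passed with the transgene, and by fry 3 in the knockout and 0 with the transgene. Leaving out 1 library gave 11 to 13 and 10 to 12.

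Deviations of same-numbered libraries from their group means correlated at -0.024, -0.011, -0.011, 0.081 and 0.003 over genes. These values cannot settle whether the replicate numbers pair the samples. Deviations within near-identical wild types are small, and those of the WT_FvB pair mirror each other (0.081 and -0.081 against Tg_FvB replicate 1). With the replicate block the transgene counts were 808 and 769, the correlation -0.083, the opposite genes 609, and Kat6b in the knockout passed at -0.43. The shallowest library was Tg_FvB replicate 4 with 12336303 counts, whose effect through depth was not told apart from that of its profile.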

Other observations

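No test in this part was chosen after the result was seen.

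Transcripts of other cell types were scarce but present. Endothelial genes, with Plvap highest in every library, summed to 16.1 to 17.8 CPM in WT_B6 and 19.4 to 30.5 CPM in KO_B6, and to 23.3 to 24.4 CPM in WT_FvB and 15.8 to 21.6 CPM in Tg_FvB. That list did not pass camera in the knockout (adjusted p = 0.382) and passed with the transgene (adjusted p = 0.0295) only at the preset correlation. Meningeal fibroblast and pericyte genes summed to 107 to 264 CPM, led by Cspg4, which oligodendrocyte precursors also express, or by Prrx1. The 12 neural crest and Schwann cell genes, a list that shares members with the oligodendrocyte one, summed to 71.3 to 296 CPM, with 207 to 212 CPM in WT_B6 and 71.3 to 145 CPM in KO_B6, but this list did not pass camera in the knockout (adjusted p = 0.105). The 39 Hox genes, which mark more posterior tissue, summed to at most 0.131 CPM, and none passed the low-count filter. Choroid plexus and hem genes summed to 2.66 to 11.8 CPM, highest in KO_B6 replicate 4 with 9.55 CPM of Otx2, and erythroid genes to 0.246 to 1.06 CPM. Only 2 microglia, 4 choroid plexus and 2 erythroid genes were measured, so these lists were not tested.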
